A study of Mus musculus with 14 samples.

How the data were processed

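The study measured messenger RNA in mouse Langerhans cells (LC) and reference populations sorted from tissue, in 14 libraries. Per the labels, 4 libraries came from CD103+ mucosal LC, 4 from CD11b+ mucosal LC, 2 from skin LC, 2 from lung dendritic cells (DC) positive for langerin and CD103, and 2 from lung macrophages. CD103 is the integrin encoded by Itgae, CD11b the integrin encoded by Itgam, and langerin the lectin encoded by Cd207. Libraries were made from the 3' end of polyadenylated RNA, and indexed cDNAs were pooled before second strand synthesis and amplification. The labels give replicate numbers but do not say that replicates were separate animals. All p-values below therefore measure only the spread between these libraries, which may be technical. The macrophage libraries carry the names of an earlier deposit, so batch and cell type cannot be separated in any comparison with them.

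The deposited table lists 16166 genes and holds 1 score per gene and library, a normalised read count that the authors rounded to whole numbers. The submitters named bcl2fastq 2.15.0.4, TopHat and the mm9 genome build, but not the tool that counted or normalised the reads. An unrounded column with the highest value of each gene showed what 1 read was worth in each library. With a tolerance of 0.05 reads, 100% of those maxima were whole multiples of that step. The inverse steps matched median-ratio size factors recomputed from the table, with ratios between 0.9931 and 1.007. The recovered depth ran from 593606 reads in CD103+ mucosal LC replicate 3 to 1377200 reads in lung macrophage replicate 1. In simulated data 93.83% of the read counts, zeros included, came back exactly from the rounded values, so the recovered reads are approximate. At such depths a value of a few reads was seldom told apart from 0, and a gene listed at 0 may be expressed at a low level. In 27 sets, 60 genes had identical values in all libraries, which leaves open how reads were shared among them.

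The deposited values were normalised and rounded, so the test planned for normalised values was taken, and of models for counts only voom on the recovered reads was run, as an alternative. Values were used on the authors' scale, a pseudocount of 4 was added and log2 was taken. Genes with at least 10 CPM (reads scaled to a common library total) in at least 2 libraries were tested, 9069 genes in the 12 libraries of LC and DC and 9622 genes in all 14 libraries. One mean per group was fitted with limma 3.58.1 in R 4.3.3, with a trend of the spread on the level and robust moderation. The 6 comparisons among LC and DC came from the 12-library model, with 8 residual degrees of freedom. The 4 comparisons with macrophages came from the 14-library model, with 9. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. In groups of 2 libraries the spread was borrowed from the other groups, and where 1 of them was left out, the lone library was assumed to vary like the others. Values in the text are group means with the SD, and fold changes are on the log2 scale with their standard error (SE).

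Gene lists of known function were fixed before the data were examined, 19 for cell programmes, 1 of immediate-early and stress genes for the quality of the cells, and 12 for other cell types that a sort could hold. The first 20 were tested in each comparison with camera from limma, at a preset correlation of 0.01 between genes, and adjusted over the 20 lists. The same test was repeated with the correlation estimated from the data. Counts of called list members are given over all genes tested and adjusted over the list alone. The other cell types were keratinocytes and oral epithelium, T cells, B cells, NK cells, neutrophils, mast cells and basophils, plasmacytoid DC, lung epithelium, fibroblasts, endothelium, melanocytes and erythroid cells. For these, the share of each library's normalised reads was computed.

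Genes were named by a rule fixed before the data were examined. It took the sorting and identity markers Cd207, Itgae, Itgam and Epcam in every comparison. It also took called genes with no overlap between the groups and a mean of at least 50 CPM in the higher group, ranked by fold change. The first 10 in each direction were taken between the mucosal subsets and the first 5 in every other comparison, without unnamed gene models, ribosomal and mitochondrial genes. Up to 4 members of each list with the smallest p were added. Genes outside the rule are named as chosen after their values were seen.

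Each mucosal library was correlated with the mean log2 profile of lung DC, skin LC and lung macrophages over 9622 genes. The difference between the subsets was tested with a two-sided exact permutation test over the 70 splits of 4 against 4 libraries, adjusted over the 3 references. Fold changes of 2 reference contrasts were also correlated across genes with the mucosal contrast, and the 200 genes most raised and 200 most lowered in each reference contrast were tested as lists. The test of such a correlation counted how many of the 35 splits of the 8 mucosal libraries gave one as large.

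Alternatives fixed before the data were examined were quantile normalisation, no filter on low values, limma without the trend, pseudocounts of 1 and 16, only the libraries of the groups compared, all 14 libraries in place of 12, replicate number as a block, and leaving out each library in turn. Added after the data were seen were limma voom on the recovered reads, scaling to a common total, covariates for epithelial and for skin LC transcripts, and leaving out 4 libraries high in epithelial transcripts. The tests were checked on simulated data of the same depth and group sizes. The simulated reads had the same dispersion for every gene (0.0167) and no structure shared between libraries. Among the mucosal subsets they recovered 91% of genes changed 2-fold and 100% of those changed 4-fold, with 12 false calls among 203. Between the lung macrophage and lung DC groups they recovered 62% and 100%. These rates may not hold for the real mucosal libraries, which shared structure such as that of the epithelial transcripts. The figures were drawn with Python 3.11.15 and matplotlib 3.10.9.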

Results

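Langerin transcripts (Cd207) were found in all LC and DC groups and were listed at 0 in lung macrophages. Skin LC had the highest level, at 11020 ± 1110 normalised reads (SD, n = 2), against 4398 ± 1020 in CD103+ mucosal LC (n = 4), 3846 ± 1070 in CD11b+ mucosal LC (n = 4) and 1458 ± 44.5 in lung DC (n = 2). Epcam, an adhesion molecule of LC and epithelia, followed the same order of tissues, with 277 ± 48.2 and 295 ± 46.7 in the mucosal subsets, 372 ± 36.8 in skin LC and 79.5 ± 3.54 in lung DC. Itgae, the gene of CD103, was highest in lung DC at 744 ± 85.6 and lower in both mucosal subsets and in skin LC (29.5 ± 12). Itgam, the gene of CD11b, ranged from 2.5 ± 2.12 in lung DC to 71 ± 5.66 in skin LC. The mucosal libraries correlated with each other at a mean r of 0.942 between the subsets, across genes, against 0.938 within CD103+ and 0.947 within CD11b+ LC. They correlated with skin LC at 0.895 and 0.892, with lung DC at 0.797 and 0.778, and with lung macrophages at 0.62 and 0.622. Among the 12 LC and DC libraries, the first principal component held 50.5% of the variance and the second 21.8%.

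**Figure D1:**
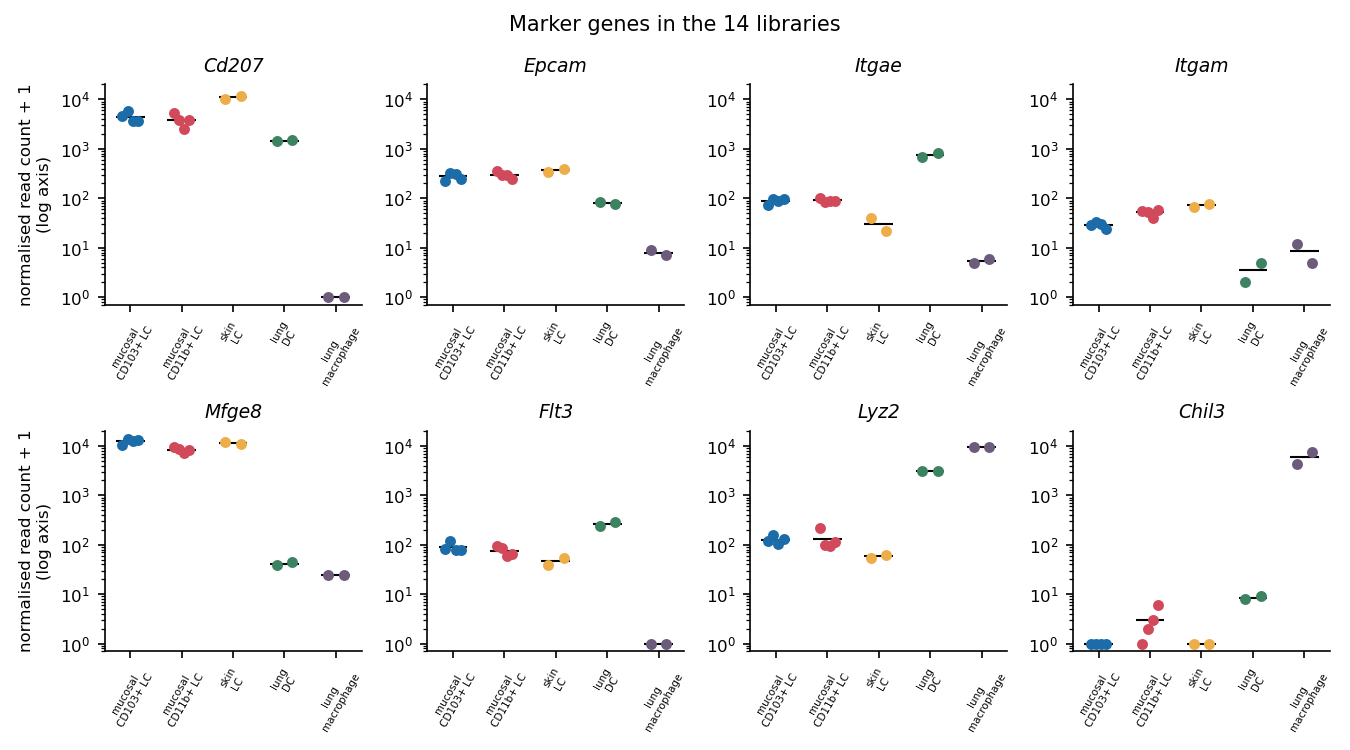
Normalised read counts of 8 marker genes in each of the 14 libraries, with 1 added and on a log axis; points are libraries and lines are group means. Cd207 was listed at 0 in both lung macrophage libraries and lay highest in the 2 skin LC libraries.

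The CD103+ mucosal subset had higher levels of Irf8 and Xcr1, and the CD11b+ subset had higher levels of Tmem176b. Irf8, a transcription factor that type 1 conventional DC (cDC1) need to develop, stood at 329 ± 45.3 normalised reads in CD103+ LC and 107 ± 17.6 in CD11b+ LC (SD, n = 4 each), a log2 fold change of 1.59 (SE 0.14, adjusted p = 2.5e-07). Xcr1, a chemokine receptor typical of cDC1, stood at 22.8 ± 6.02 and 3.5 ± 2.52 (log2 fold change 1.86, SE 0.25, adjusted p = 0.00013). Tmem176b, a membrane protein of myeloid cells, fell by 1.27 on the log2 scale in CD103+ relative to CD11b+ LC (SE 0.17, adjusted p = 0.00013), with 62.3 ± 19.1 against 153 ± 20.6. Mgl2, a lectin that binds galactose-type sugars, stood at 82 ± 12.4 in CD103+ LC and 162 ± 37.3 in CD11b+ LC (log2 fold change -0.93, SE 0.17, adjusted p = 0.0056), a call lost without a trend of the spread (adjusted p = 0.11).

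Of 9069 genes tested, 44 differed between the mucosal subsets, 30 higher and 14 lower in CD103+ LC. Of these, 23 changed at least 2-fold, and 746 genes had an unadjusted p under 0.05. The 44 calls became 67 without CD103+ replicate 1, 28 without CD11b+ replicate 3, 14 without a trend of the spread and 20 when all 14 libraries shared 1 estimate of the spread. Among the genes higher in CD103+ LC were Dnase1l3, a secreted DNase of myeloid cells (106.5 ± 17.6 against 32.8 ± 10.9, log2 fold change 1.62, SE 0.19), and Mpeg1, a pore-forming protein of phagocytes (80.3 ± 5.62 against 31.5 ± 7.23, 1.27, SE 0.16). Basp1, a membrane-bound signalling protein, was at 565 ± 57.6 against 264 ± 49.1, and Zmynd15, a transcriptional repressor, at 798 ± 102 against 395 ± 48.9, with log2 fold changes of 1.09 (SE 0.13) and 1.01 (SE 0.14). The chemokine gene Ccl17 and the kinase gene Map4k4 were higher by 0.92 (SE 0.15) and 0.86 (SE 0.16). The chemokine gene Ccl3 (63.5 ± 17.5 against 120 ± 10) and H2-Oa, which encodes a chain of a regulator of peptide loading on MHC class II (66.8 ± 8.85 against 123 ± 28.6), were lower by -0.92 (SE 0.18) and -0.82 (SE 0.16). These genes had adjusted p-values of at most 0.0099, and none of their values overlapped between the subsets, as the naming rule required. Without the trend, however, Ccl17, Map4k4, Ccl3 and H2-Oa lost the call (adjusted p = 0.11 to 0.12), as did Ccl17 (0.15) and H2-Oa (0.16) with all 14 libraries. Other calls were lost under more settings, and without the trend the 5 genes named next all lost it, at 0.067 to 0.2. The enzyme gene Il4i1 (87 ± 41.1 against 23.5 ± 6.95, log2 fold change 1.63) reached adjusted p = 0.068 without CD11b+ replicate 3 and 0.076 without CD11b+ replicate 4. With replicate number as a block, only the 8 mucosal libraries, or voom on the recovered reads it reached 0.11 to 0.13, and it shares all its values with the read-through gene Nup62-il4i1. The chemokine gene Cxcl9 (94.8 ± 45.2 against 31 ± 6.48, 1.39) reached 0.059 without CD11b+ replicate 4, and 0.15 with voom or with only the 8 mucosal libraries. The lectin gene Cd209d (20.8 ± 6.6 against 53.5 ± 12, -1.23) reached 0.059 without CD103+ replicate 3 and 0.072 without CD11b+ replicate 3, and Lmo1, a transcriptional cofactor (-1.02), reached 0.057 without CD11b+ replicate 2. Hpgd, which inactivates prostaglandins (53 ± 16.1 against 91.5 ± 10.4, -0.79, adjusted p = 0.043), lost the call without any 1 of the 8 mucosal libraries except CD103+ replicate 1, at 0.068 to 0.21.

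**Figure D2:**
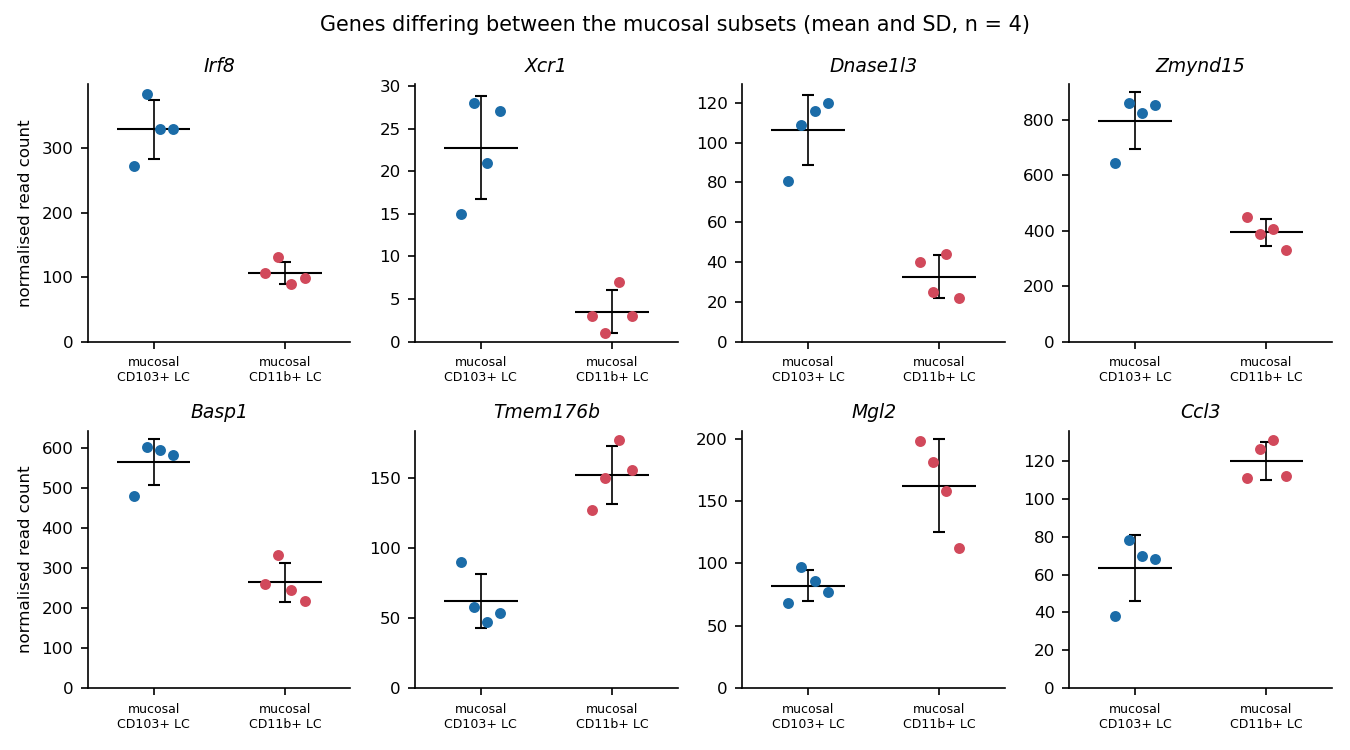
Normalised read counts of 8 genes called between the mucosal subsets, 1 point per library, with the mean and SD of 4 libraries per subset. Irf8 and Xcr1 lay higher in every CD103+ library, and Tmem176b, Mgl2 and Ccl3 higher in every CD11b+ library.

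The genes of the sorting and identity markers did not pass the test between the mucosal subsets. Itgae was at 88 ± 11.1 in CD103+ LC and 89.5 ± 7.55 in CD11b+ LC, a log2 fold change of -0.03 with a 95% confidence interval from -0.34 to 0.28 (adjusted p = 0.99). Itgam was at 28 ± 3.74 and 50.8 ± 8.77 without overlap, a log2 fold change of -0.77 (SE 0.2) that did not pass the test (adjusted p = 0.1), though it did with a pseudocount of 16 (adjusted p = 0.044). Cd207 (0.21, SE 0.2, adjusted p = 0.87) and Epcam (-0.09, SE 0.14, adjusted p = 0.93) did not pass either.

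Among the gene lists, camera called 5 of 20 between the mucosal subsets. Of the 35 splits of the 8 mucosal libraries, however, 9 called as many lists, the labelled split among them, so chance could not be excluded. The cDC1 list rose in CD103+ LC, with 2 of 18 members higher (Irf8 and Xcr1), none lower and 5 higher when adjusted over the list alone. Its camera adjusted p was 8.4e-10, and adjusted p = 0.051 with an estimated correlation. Batf3, a partner of Irf8 in cDC1, was at 67.5 ± 11.9 against 37.3 ± 5.44 and missed the threshold (adjusted p = 0.055, and 0.015 without CD103+ replicate 1). The list of migratory DC genes, active in DC that leave for lymph nodes, rose with 4 of 23 members higher (Ccl17, Il4i1, Marcks and Serpinb6b), none lower and 12 higher when adjusted over the list alone. Its adjusted p was 1.5e-11, and adjusted p = 0.04 with an estimated correlation. Of these, Marcks lost its call without CD103+ replicate 3 (adjusted p = 0.088) or CD11b+ replicate 4 (0.076), and Serpinb6b without CD103+ replicate 2 (0.054) or 4 (0.052) or CD11b+ replicate 1 (0.059) or 3 (0.066). The list of genes shared by conventional DC rose with 2 of 17 members higher (Tbc1d8 and Ass1), none lower and 5 higher when adjusted over the list alone. Its adjusted p was 9.4e-05, and adjusted p = 0.039 with an estimated correlation. Tbc1d8, a regulator of vesicle traffic, was at 27 ± 3.65 against 9.5 ± 1.73, while Ass1 lost its call without CD103+ replicate 3 (0.055) or 4 (0.072) or CD11b+ replicate 4 (0.059). Ass1, Marcks and Serpinb6b also lost it without the trend (0.093 to 0.17) and with all 14 libraries (0.32 to 0.75). The MHC class I presentation list rose with none of 20 members called and 3 higher when adjusted over the list alone. Its adjusted p was 1.3e-06, and adjusted p = 0.21 with an estimated correlation. The list of type 2 conventional DC (cDC2) genes fell in CD103+ LC, with 1 of 11 members lower (Mgl2), none higher and 3 lower when adjusted over the list alone. Its adjusted p was 0.00042, and adjusted p = 0.051 with an estimated correlation. Sirpa, an inhibitory receptor of cDC2 and macrophages, was at 113 ± 7.79 and 162 ± 13.4 and was not called (adjusted p = 0.18). The other 15 lists were not called, among them the LC markers (adjusted p = 0.1), the macrophage core genes (0.13), the monocyte genes (0.91) and the cell cycle (0.61).

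Transcripts of stratified epithelium were present in the mucosal libraries and varied between them. The keratinocyte and oral epithelium genes made up 1.43 ± 1.32% of the reads in CD103+ LC and 1.70 ± 0.917% in CD11b+ LC (SD, n = 4 each), with a range from 0.273 to 3.32% over the 8 libraries, and no difference between the subsets was detected (two-sided exact permutation p = 0.657). Their share was 0.179% in skin LC, 0.00271% in lung DC and 0.0177% in lung macrophages. With the epithelial level of each library as a covariate, 65 genes were called, among them all of the 44, while 16 genes were called without the 4 libraries highest in these transcripts. That left 3 CD103+ libraries against CD11b+ replicate 1 alone, which was assumed to vary like the other groups, so it tests little. The covariate tests little as well, since no difference in the epithelial share between the subsets was detected.

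**Figure D3:**
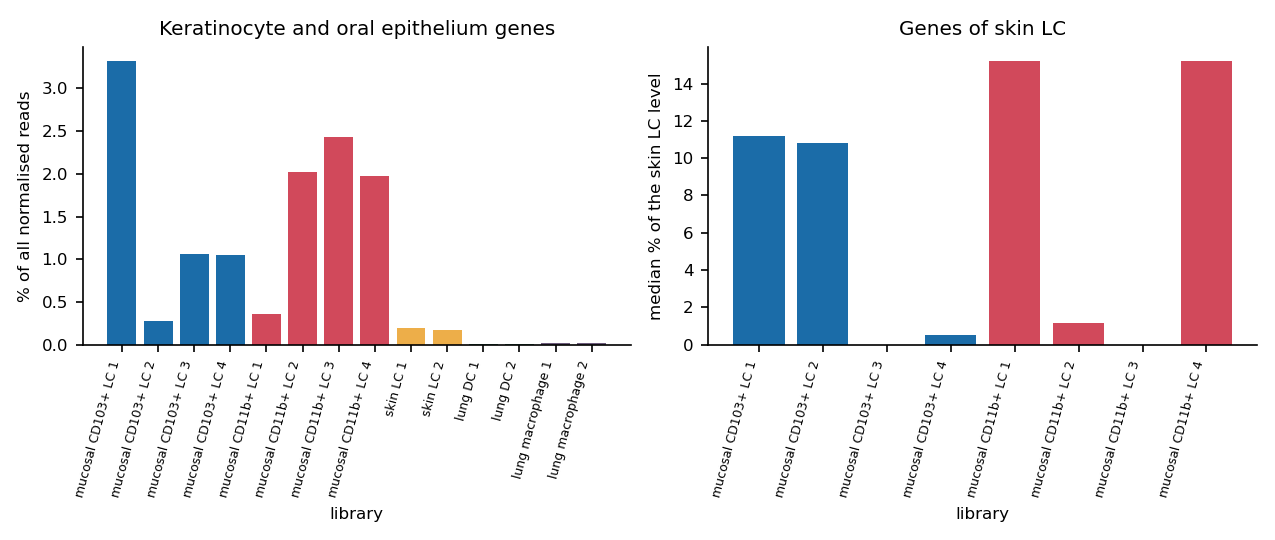
Left, share of each library's normalised reads in keratinocyte and oral epithelium genes. Right, median level of 8 genes of the skin LC libraries in each mucosal library, as a percentage of their skin LC level. Bars are single libraries, coloured by group, and 4 mucosal libraries lay between 10.8 and 15.2% on the right.

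The profile correlations did not place either mucosal subset nearer to a reference population. The mean r with lung DC was 0.801 ± 0.0337 for CD103+ and 0.781 ± 0.0237 for CD11b+ LC (n = 4 each, two-sided exact permutation p = 0.429, adjusted p = 0.914). With skin LC it was 0.901 ± 0.0244 and 0.898 ± 0.0288 (exact permutation p = 0.886), and with lung macrophages 0.633 ± 0.0222 and 0.635 ± 0.0146 (exact permutation p = 0.914), each with an adjusted p of 0.914. The sign of the last 2 small differences turned when single libraries were left out. For skin LC it turned without CD103+ replicate 2 (-0.0084), CD11b+ replicate 2 (-0.0023) or CD11b+ replicate 3 (-0.0077), and for macrophages without CD103+ replicate 1 (0.0092) or CD11b+ replicate 1 (0.0051). The r with lung DC was lower in libraries with more epithelial transcripts. It was 0.827 in CD103+ replicate 2 and 0.816 in CD11b+ replicate 1, with epithelial shares of 0.273 and 0.355%. In CD103+ replicate 1 and CD11b+ replicate 3, with 3.32 and 2.43%, it was 0.752 and 0.764. Such variation within the subsets could hide a difference between them.

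Fold changes between lung DC and skin LC were compared with those between CD103+ and CD11b+ mucosal LC. Across 9069 genes, which are not independent replicates, the correlation was 0.148, and 7 of the 35 splits of the mucosal libraries gave one as large (permutation p = 0.2, adjusted over the 2 contrasts 0.2). Of 36 genes called in both contrasts, 25 had the same sign and 11 the opposite. The 200 genes most raised in lung DC over skin LC were higher in CD103+ LC as a set (median log2 fold change 0.15, camera p = 2.6e-07, and p = 0.013 with an estimated correlation), and the 200 most lowered were not shifted (p = 0.26). Between lung macrophages and lung DC on one side and CD11b+ and CD103+ LC on the other, the correlation was 0.162 over 9622 genes. No other split of the 35 gave one as large (permutation p = 0.0286, the smallest these splits can give), and adjusted over the 2 contrasts the permutation p was 0.0571. The unadjusted permutation p was no longer past the threshold without CD103+ replicate 2, 3 or 4 or CD11b+ replicate 3 or 4, at 0.0571 to 0.114. The correlations were then 0.114, 0.164 and 0.154 without those CD103+ replicates, and 0.123 and 0.149 without those CD11b+ replicates. The 200 genes most raised in macrophages over lung DC had a median log2 fold change of 0.06 in CD11b+ over CD103+ LC (camera p = 0.044, and p = 0.19 with an estimated correlation), with none of them called. The 200 most lowered were lower in CD11b+ LC (median log2 fold change -0.18, camera p = 6.6e-11, and p = 0.009 with an estimated correlation).

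Both mucosal subsets had higher levels of Mfge8, Ltc4s and Csf1r than lung DC and lower levels of Il12b, Ccl17 and Naaa. Mfge8, which tethers apoptotic cells to phagocytes, was at 12580 ± 1460 in CD103+ LC, 8394 ± 890 in CD11b+ LC (SD, n = 4 each) and 40.5 ± 3.54 in lung DC (n = 2). Its log2 fold changes against lung DC were 8.14 and 7.56 (SE 0.13 each, adjusted p = 2e-24 and 1.2e-23). Ptgs1, the constitutive cyclooxygenase, was at 870.5 ± 135 in CD103+ LC and 2 ± 1.41 in lung DC (adjusted p = 2.2e-21). Ltc4s, the leukotriene C4 synthase, was at 1015 ± 137 and 915 ± 183 in the mucosal subsets and 22.5 ± 0.707 in lung DC, and Csf1r, the receptor of CSF1 and IL-34, at 1197 ± 195, 1188 ± 198 and 39 ± 8.49. Lung DC had more Il12b, a chain of interleukin 12 (1048 ± 213 against 16.8 ± 4.72 and 4 ± 1.41), more Ccl17 (6020 ± 129 against 289 ± 45.6 and 153 ± 40.2) and more Naaa, a lysosomal amidase (1550 ± 148 against 41.8 ± 11.4 and 34 ± 3.65).

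Between CD103+ mucosal LC and lung DC, 2774 of 9069 genes differed, 1327 higher and 1447 lower in the mucosal cells, and between CD11b+ LC and lung DC 2972 genes, 1477 of them higher in the mucosal cells. Scaled to a common total, the splits were 2045 higher and 941 lower for CD103+ LC, and 2360 higher of 3335 for CD11b+ LC, since that scaling moved the median gene by 0.26 and 0.30 on the log2 scale. With voom on the recovered reads they went the other way, 1017 higher and 1561 lower for CD103+ LC and 1088 and 1602 for CD11b+ LC. The count for CD103+ LC was 1654 without lung DC replicate 1 and 1613 without replicate 2, and that for CD11b+ LC 1770 and 1723.

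Of the cDC1 list, 17 of 18 members were lower in CD103+ LC than in lung DC and none higher (18 lower when adjusted over the list alone, adjusted p = 6.9e-18, and adjusted p = 0.011 with an estimated correlation). The same numbers of members differed in CD11b+ LC (17 lower when adjusted over the list alone, adjusted p = 2.1e-19, and adjusted p = 0.012 with an estimated correlation). Itgae was lower by -3.03 (SE 0.19) in CD103+ and -3.00 (SE 0.19) in CD11b+ LC, and Xcr1 by -3.25 (SE 0.31) and -5.11 (SE 0.31). Irf8 was at 922 ± 202 in lung DC, with a log2 fold change of -3.06 (SE 0.17) in CD11b+ LC. The LC markers rose in CD103+ LC, with 8 of 14 members higher and 1 lower, the same numbers when adjusted over the list alone (adjusted p = 1e-05, and adjusted p = 0.01 with an estimated correlation). In CD11b+ LC 8 were higher and 2 lower, and 9 and 3 when adjusted over the list alone (adjusted p = 7.5e-05, and adjusted p = 0.013 with an estimated correlation). Cdh1, the E-cadherin that anchors LC to epithelium, was at 208 ± 57 and 237 ± 19 in the mucosal subsets and 1.5 ± 0.707 in lung DC. Cd207 was higher by 1.56 (SE 0.25, adjusted p = 0.00045) and 1.35 (SE 0.25, adjusted p = 0.0013).

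Of the genes shared by conventional DC, 14 of 17 were lower and none higher in each mucosal subset than in lung DC, with the same numbers when adjusted over the list alone. The adjusted p was 6e-07 for CD103+ and 2.6e-08 for CD11b+ LC, and adjusted p = 0.0089 and 0.0051 with an estimated correlation. Among them were Tbc1d8 (-3.08, SE 0.25, and -4.28, SE 0.25) and Btla, an inhibitory receptor (-3.94, SE 0.33, and -4.08, SE 0.33). The migratory DC genes fell, with 13 of 23 lower in CD103+ LC (14 when adjusted over the list alone, adjusted p = 1e-05, and adjusted p = 0.086 with an estimated correlation). In CD11b+ LC 17 were lower, also when adjusted over the list alone (adjusted p = 2.4e-09, and adjusted p = 0.039 with an estimated correlation). Ccr7, the receptor that guides DC to lymph nodes, was lower by -2.11 (SE 0.28) and -3.05 (SE 0.28). The cDC2 list rose, with 7 of 11 higher and 4 lower in CD103+ LC, the same when adjusted over the list alone (adjusted p = 0.0098, and adjusted p = 0.1 with an estimated correlation). In CD11b+ LC 7 were higher and 3 lower by both counts (adjusted p = 0.0014, and adjusted p = 0.053 with an estimated correlation). S100a4, a calcium-binding protein, was at 5022 ± 802 and 5218 ± 811 against 209 ± 33.9, and Sirpa at 113 ± 7.79 and 162 ± 13.4 against 1 ± 1.41. Ccr2, a monocyte receptor in the same list, was lower in both subsets (-4.64, SE 0.31, and -4.36, SE 0.31).

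The macrophage core genes rose, with 15 of 23 higher and 5 lower in CD103+ LC (16 and 5 when adjusted over the list alone, adjusted p = 1e-05, and adjusted p = 0.077 with an estimated correlation). In CD11b+ LC 16 were higher and 5 lower (17 and 5, adjusted p = 2.8e-06, and adjusted p = 0.053 with an estimated correlation). C1qa, a chain of complement C1q, was at 386 ± 70 and 405 ± 57.4 against 4 ± 0, and Dok3, an adaptor protein, at 686 ± 154 and 606 ± 68.7 against 14 ± 4.24. The MHC class I presentation list fell, with 12 of 20 lower in CD103+ LC (14 when adjusted over the list alone, adjusted p = 3.3e-05, and adjusted p = 0.21 with an estimated correlation). In CD11b+ LC 16 were lower (17, adjusted p = 1.6e-07, and adjusted p = 0.11 with an estimated correlation). Psme1, a proteasome activator, was lower by -1.43 (SE 0.15) and -1.71 (SE 0.15). The inflammatory list fell, with 5 of 25 higher and 17 lower in CD103+ LC by both counts (adjusted p = 3e-04, and adjusted p = 0.12 with an estimated correlation). In CD11b+ LC 5 were higher and 16 lower (5 and 17, adjusted p = 0.00037, and adjusted p = 0.12 with an estimated correlation). Traf1, a signalling adaptor, was lower by -2.25 (SE 0.21) and -2.88 (SE 0.21). Of the TGF-beta and BMP list, 10 of 20 were lower and none higher in CD103+ LC (11 when adjusted over the list alone, adjusted p = 0.0067, and adjusted p = 0.056 with an estimated correlation). In CD11b+ LC 2 were higher and 10 lower (2 and 11, adjusted p = 0.0057, and adjusted p = 0.044 with an estimated correlation). Tgfbi, a TGF-beta target, was lower by -2.56 (SE 0.2) and -2.06 (SE 0.2). The chemokine receptor list fell, with 2 of 11 higher and 7 lower in CD103+ LC by both counts (adjusted p = 0.0098, and adjusted p = 0.073 with an estimated correlation). In CD11b+ LC 3 were higher and 7 lower by both counts (adjusted p = 0.027, and adjusted p = 0.081 with an estimated correlation). These calls were lost without lung DC replicate 1 (adjusted p = 0.066 and 0.16) or 2 (0.11 and 0.23).

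Genes of stratified epithelium stood among the largest differences from lung DC. Krt4, a keratin of oral epithelium, was at 3706 ± 3350 in CD103+ LC, 3812 ± 1920 in CD11b+ LC and 0.5 ± 0.707 in lung DC, and Krt14 and the metallothionein gene Mt4 were listed at 0 in lung DC. Of the keratinocyte and oral epithelium list, 16 of 19 members were higher in CD103+ LC and 18 in CD11b+ LC, and none were lower. The calls of Krt4, Krt14 and Mt4 were lost with voom on the recovered reads, at adjusted p-values from 0.41 to 0.55. Lung DC carried the surfactant gene Sftpc at 286 ± 49.5, against 0.75 ± 1.5 and 1.5 ± 2.38 in the mucosal subsets.

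Both mucosal subsets had higher levels of Ube2c, Bst2 and Ccl17 than skin LC and lower levels of Il18 and Cd207. Ube2c, a ubiquitin-conjugating enzyme of mitosis, was at 79.3 ± 20.7 in CD103+ LC, 75.5 ± 24.8 in CD11b+ LC (SD, n = 4 each) and 8 ± 2.83 in skin LC (n = 2), with log2 fold changes of 2.78 (SE 0.27, adjusted p = 2.3e-07) and 2.69 (SE 0.27, adjusted p = 3.9e-07). Bst2, an antiviral protein induced by interferon, was at 254 ± 53.4 in CD11b+ LC against 81 ± 9.9. Ccl17 was at 289 ± 45.6 and 153 ± 40.2 against 34 ± 8.49. Il18, a cytokine of the interleukin 1 family, was higher in skin LC, at 187 ± 25.5 against 18.5 ± 9.26 and 20.3 ± 8.81. Cd207 was lower in the mucosal subsets by -1.35 (SE 0.25, adjusted p = 0.0029) and -1.56 (SE 0.25, adjusted p = 0.0011), and Itgae was higher, by 1.53 (SE 0.19) in CD11b+ LC.

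Between CD103+ LC and skin LC, 1610 genes differed, 766 higher and 844 lower in the mucosal cells, and between CD11b+ LC and skin LC 1727 genes, 807 higher and 920 lower. Scaled to a common total, the splits were 942 and 631 and 1153 and 646, with median shifts of 0.11 and 0.15, and with voom on the recovered reads they were 507 and 922 and 460 and 963. The counts were 855 and 844 without skin LC replicate 1, 664 and 650 without skin LC replicate 2, and 1348 and 1021 with the epithelial level as a covariate.

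Of the cell cycle list, 23 of 32 members were higher and none lower in each mucosal subset than in skin LC, with 24 for CD103+ and 26 for CD11b+ LC when adjusted over the list alone. The adjusted p was 9.5e-11 for CD103+ and 2.6e-11 for CD11b+ LC, and adjusted p = 0.069 and 0.12 with an estimated correlation. Keratinocyte and oral epithelium genes such as Krt4 also took more of the reads in the mucosal subsets, at 1.43 and 1.70% against 0.179%. With the epithelial level of each library as a covariate, the adjusted p of the cell cycle list was 1e-10 and 7.6e-11. Examples were Ccnb2, a mitotic cyclin (2.53, SE 0.32, and 2.29, SE 0.32), and Birc5, an inhibitor of apoptosis needed in mitosis (2.03, SE 0.27, and 1.92, SE 0.27). The interferon response list rose, with 13 of 22 higher in CD103+ LC (17 when adjusted over the list alone, adjusted p = 3.6e-10, and adjusted p = 0.082 with an estimated correlation). In CD11b+ LC 11 were higher (15, adjusted p = 1e-07, and adjusted p = 0.12 with an estimated correlation). Irf7, a transcription factor of the interferon response, was higher by 2.19 (SE 0.33) in CD103+ LC. The MHC class I presentation list rose, with 15 of 20 higher in CD103+ LC (16 when adjusted over the list alone, adjusted p = 1.5e-09, and adjusted p = 0.086 with an estimated correlation). In CD11b+ LC 8 were higher by both counts (adjusted p = 8.4e-05, and adjusted p = 0.31 with an estimated correlation). Nlrc5, the transactivator of MHC class I genes, was at 31 ± 4.32 and 24.3 ± 8.14 against 2 ± 2.83. The chemokine ligand list rose, with 9 of 16 higher and 5 lower in CD103+ LC (10 and 5 when adjusted over the list alone, adjusted p = 0.0021, and adjusted p = 0.086 with an estimated correlation). In CD11b+ LC 9 were higher and 4 lower (10 and 4, adjusted p = 0.0032, and adjusted p = 0.12 with an estimated correlation). Cxcl9 was at 94.8 ± 45.2 in CD103+ LC and 4.5 ± 0.707 in skin LC (3.42, SE 0.32), and Ccl3 at 120 ± 10 in CD11b+ LC and 23 ± 2.83 in skin LC (2.20, SE 0.22).

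The chemokine receptor list rose, with 5 of 11 higher and 1 lower in each mucosal subset by both counts. Its adjusted p was 0.008 for CD103+ and 0.011 for CD11b+ LC, and adjusted p = 0.082 and 0.12 with an estimated correlation. Ccr7 was higher by 2.70 (SE 0.28) and 1.75 (SE 0.28), and Ccrl2, a receptor for chemerin, was lower by -1.45 (SE 0.18) and -0.95 (SE 0.18). The cDC1 list rose, with 11 of 18 higher and 1 lower in CD103+ LC by both counts (adjusted p = 4.4e-07, and adjusted p = 0.086 with an estimated correlation). In CD11b+ LC 6 were higher and 2 lower by both counts (adjusted p = 0.028, and adjusted p = 0.47 with an estimated correlation). The CD11b+ call was lost without CD11b+ replicate 1 (adjusted p = 0.081). Irf8 was at 112 ± 3.54 in skin LC and higher in CD103+ LC by 1.52 (SE 0.17), and Batf3 was higher by 2.25 (SE 0.23) and 1.47 (SE 0.23). In CD103+ LC the genes shared by conventional DC rose, with 9 of 17 higher and 2 lower (10 and 2 when adjusted over the list alone, adjusted p = 0.00087, and adjusted p = 0.069 with an estimated correlation). Amica1, a junctional adhesion molecule, was higher by 2.89 (SE 0.2). The migratory DC genes also rose there, with 10 of 23 higher and 4 lower (11 and 4, adjusted p = 0.0076, and adjusted p = 0.24 with an estimated correlation). Fscn1, an actin-bundling protein of mature DC, was at 79.8 ± 45.2 against 3.5 ± 0.707 and lost its call without skin LC replicate 1 (adjusted p = 0.058) or 2 (0.086). In CD11b+ LC the LC markers fell, with 5 of 14 lower and none higher by both counts (adjusted p = 0.021, and adjusted p = 0.12 with an estimated correlation). Ltc4s was lower by -1.39 (SE 0.16) and Csf1r by -0.92 (SE 0.17). Cybb, the catalytic chain of the phagocyte oxidase, was at 68.5 ± 10.5 in CD11b+ LC and 4.5 ± 4.95 in skin LC, and Ly6a, the surface protein Sca-1, at 458 ± 71 and 50 ± 12.7. The transcriptional regulator Crem and the scaffold gene Grasp were lower in CD11b+ LC by -2.99 (SE 0.29) and -2.96 (SE 0.38).

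Some of the largest differences from skin LC concerned genes that varied among the mucosal libraries. The kinase gene Wnk2 (9 ± 6.27 in CD103+ LC against 152 ± 7.07), the proteoglycan gene Podn (4.5 ± 4.43 against 68.5 ± 6.36) and the splicing factor gene Rbfox1 (3 ± 3.56 against 50 ± 1.41) were higher in skin LC. Podn and Rbfox1 belong to a set of 8 genes of the skin LC libraries, chosen by level after the values were seen. The set stood at medians of 10.8 to 15.2% of the skin level in CD103+ replicates 1 and 2 and CD11b+ replicates 1 and 4. In the other 4 mucosal libraries the medians were 0 to 1.18%. Krt76, a keratin of palate and gum (443 ± 245 against 31 ± 4.24), the transcription factor gene Barx2 and the gene Selenbp2 were called higher in CD11b+ than in skin LC (adjusted p = 0.045, 0.046 and 0.048). All 3 lost the call without CD11b+ replicate 2, 3 or 4 or either skin library, at 0.088 to 0.25. Of the keratinocyte and oral epithelium list, none of 19 members passed the test between either mucosal subset and skin LC, although the list took 1.43 ± 1.32% and 1.70 ± 0.917% of the reads against 0.179%.

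Lung DC had higher levels of cDC1 genes than skin LC and lower levels of LC marker genes. Naaa was at 1550 ± 148 in lung DC and 8 ± 7.07 in skin LC (SD, n = 2 each; log2 fold change 7.15, SE 0.32, adjusted p = 9.9e-14), Il12b at 1048 ± 213 and 2 ± 2.83, and Ccl17 at 6020 ± 129 and 34 ± 8.49 (7.33, SE 0.22, adjusted p = 2.9e-18). Ckb, the brain-type creatine kinase, was at 1684 ± 1.41 in lung DC and 1 ± 0 in skin LC. Alox5, the 5-lipoxygenase that starts leukotriene synthesis, was at 1330 ± 109 in skin LC and 0.5 ± 0.707 in lung DC. Mfge8 was lower in lung DC by -8.00 (SE 0.15, adjusted p = 1e-22), Cd207 by -2.91 (SE 0.29) and Itgam by -3.57 (SE 0.28), while Itgae was higher by 4.52 (SE 0.22).

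In this comparison 2897 genes differed, 1503 higher and 1394 lower in lung DC, and 1186 and 1690 when scaled to a common total (median shift -0.17). Of the cDC1 list, 17 of 18 were higher and 1 lower by both counts (adjusted p = 1.4e-17, and adjusted p = 0.011 with an estimated correlation). Of the genes shared by conventional DC, 11 of 17 were higher and none lower (12 when adjusted over the list alone, adjusted p = 7.7e-08, and adjusted p = 0.0063 with an estimated correlation). Examples were Amica1 (4.91, SE 0.23) and Dpp4, a surface peptidase (127.5 ± 0.707 against 1.5 ± 0.707). Of the LC markers, 8 of 14 were lower and 1 higher by both counts (adjusted p = 3.1e-06, and adjusted p = 0.008 with an estimated correlation). The chemokine receptors rose, with 7 of 11 higher and 2 lower (7 and 3 when adjusted over the list alone, adjusted p = 0.0031, and adjusted p = 0.04 with an estimated correlation). So did the TGF-beta and BMP list, with 10 of 20 higher and none lower (10 and 1, adjusted p = 0.0031, and adjusted p = 0.04 with an estimated correlation). Tgfbi was higher by 4.26 (SE 0.23) and Xcr1 was at 245 ± 17 against 1 ± 0. The MHC class I presentation list rose, with 17 of 20 higher (19 when adjusted over the list alone, adjusted p = 1.6e-10, and adjusted p = 0.059 with an estimated correlation). H2-Q7, a class I gene whose reads cannot be told from those of H2-Q9, was higher by 3.13 (SE 0.22). The cell cycle rose with 22 of 32 higher (23, adjusted p = 1.7e-07, and adjusted p = 0.059 with an estimated correlation), and Ube2c by 2.69 (SE 0.31). The migratory DC genes rose with 13 of 23 higher (13 and 1 lower, adjusted p = 9.7e-07, and adjusted p = 0.059 with an estimated correlation), and Ccr7 by 4.80 (SE 0.32). The chemokine ligands rose with 10 of 16 higher and 3 lower by both counts (adjusted p = 0.0014, and adjusted p = 0.061 with an estimated correlation). The macrophage core genes fell with 5 of 23 higher and 15 lower (5 and 16, adjusted p = 3e-05, and adjusted p = 0.062 with an estimated correlation), and C1qa by -5.66 (SE 0.2). The cDC2 list fell with 4 of 11 higher and 6 lower by both counts (adjusted p = 0.019, and adjusted p = 0.11 with an estimated correlation).

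The interferon response rose in lung DC over skin LC with 8 of 22 higher and 2 lower (9 and 2 when adjusted over the list alone, adjusted p = 0.026, and adjusted p = 0.4 with an estimated correlation). So did the inflammatory list, with 10 of 25 higher and 5 lower (11 and 5, adjusted p = 0.039, and adjusted p = 0.36 with an estimated correlation). Without lung DC replicate 2 both had adjusted p = 0.058, and without skin LC replicate 2 both had 0.054. The matrix genes Mmp9 (916.5 ± 129 in skin LC against 0.5 ± 0.707) and Col16a1 (963 ± 96.9 against 1 ± 0) were called lower in lung DC (adjusted p = 0.021 and 0.017). Both lost the call without any 1 of the 4 libraries, at 0.069 to 0.095.

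Lung macrophages had higher levels of alveolar macrophage genes than LC and DC and lower levels of Cd74. Chil3, a chitinase-like protein of alveolar macrophages, was at 5994 ± 2270 (SD, n = 2) and was listed at 0 in CD103+ and skin LC. Lpl, the lipoprotein lipase, was at 2018 ± 280 against 2 ± 1.41 in lung DC, and Lyz2, a lysozyme, at 9592 ± 72.8 against 3076 ± 7.78 in lung DC, 127 ± 22 in CD103+ LC and 58 ± 5.66 in skin LC. Cd74, the MHC class II invariant chain, was at 817 ± 75 in macrophages, 48760 ± 1430 in lung DC, 46060 ± 5240 in CD103+ LC, 42440 ± 5810 in CD11b+ LC and 54630 ± 3410 in skin LC. The macrophage libraries came from an earlier deposit, and they expressed Xist, while the other 12 libraries expressed the Y-linked gene Ddx3y, so batch, sex and cell type cannot be told apart here.

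Of 9622 genes tested, 4404 differed between macrophages and lung DC (2143 higher and 2261 lower in macrophages), 4783 between macrophages and CD103+ LC (2240 and 2543), 4815 between macrophages and CD11b+ LC (2232 and 2583) and 4630 between macrophages and skin LC (2284 and 2346). Scaled to a common total, the split against lung DC was 2748 and 1734, with a median shift of 0.19. All 22 alveolar macrophage genes were higher in macrophages than in lung DC, and 21, 21 and 20 were higher than in CD103+, CD11b+ and skin LC, with none lower and the same numbers when adjusted over the list alone. The adjusted p-values were 1.1e-20, 3.7e-21, 4.4e-21 and 1.4e-19, and at most 5.4e-05 with an estimated correlation. Ear2, a ribonuclease of the eosinophil family, was at 2614 ± 773 and was listed at 0 in CD11b+ and skin LC, and Atp6v0d2, a proton pump subunit, at 699.5 ± 141 and was listed at 0 in lung DC. Adjusted over the list alone, each count of list members in the macrophage comparisons was the same or higher by 1 or 2. The lysosome and lipid list rose in all 4 comparisons, with 23 of 29 higher and 2 lower against lung DC, 24 and 2 against CD103+ LC, 23 and 2 against CD11b+ LC and 22 and 1 against skin LC. The adjusted p-values were 3.4e-10, 2.4e-11, 1.3e-10 and 7.9e-09, and at most 0.0019 with an estimated correlation. Abcg1, a cholesterol exporter, was higher than in lung DC by 5.49 (SE 0.33), and Plin2, a lipid droplet protein, higher than in CD103+ LC by 3.08 (SE 0.18).

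**Figure D4:**
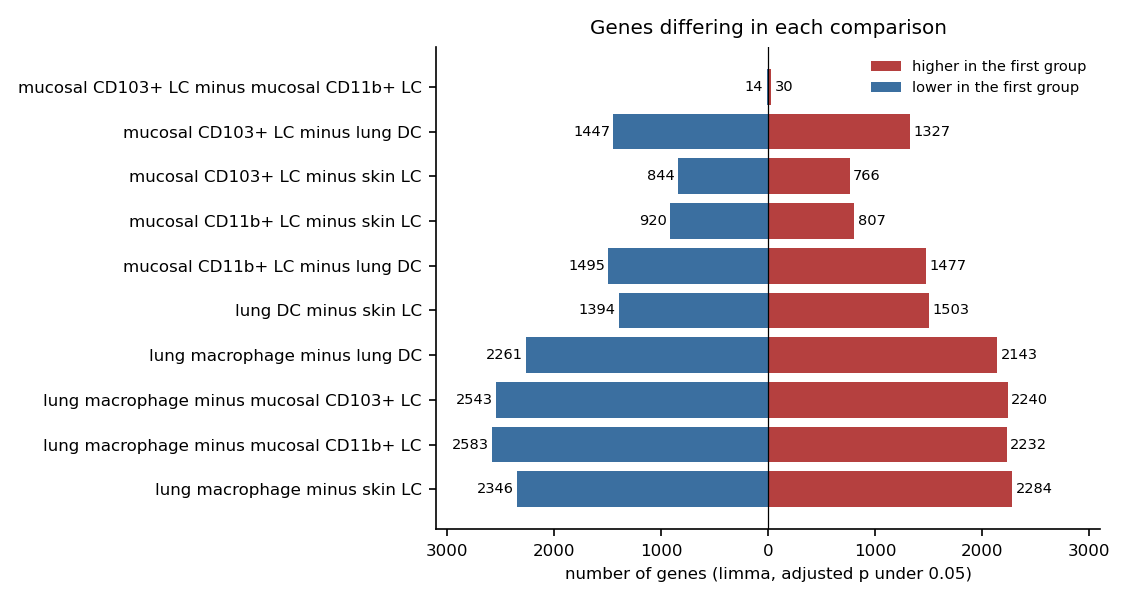
Number of genes called in each of the 10 comparisons with limma at an adjusted p under 0.05, higher (right) or lower (left) in the first group named. The mucosal subsets differed in 44 genes and each macrophage comparison in at least 4404.

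The genes shared by conventional DC fell in macrophages in all 4 comparisons. All 17 were lower than in lung DC, 15 lower than in CD103+ LC, 14 lower than in CD11b+ LC, and 12 lower and 1 higher than in skin LC. The adjusted p-values were 3.3e-12, 3.6e-08, 7.4e-07 and 7e-04, and at most 0.018 with an estimated correlation. Flt3, the growth factor receptor of DC, was listed at 0 in macrophages and was at 265.5 ± 36.1 in lung DC. The LC markers fell relative to the 3 LC groups, with 12 of 15 lower and 1 higher against CD103+ LC, 13 lower against CD11b+ LC and 11 lower and 1 higher against skin LC. The adjusted p-values were 1.9e-07, 3e-07 and 4.6e-07, and at most 0.0019 with an estimated correlation. Against lung DC, the cDC1 list fell with all 18 members lower (adjusted p = 2.7e-14, and adjusted p = 0.0083 with an estimated correlation). Against CD103+ LC 2 were higher and 11 lower (adjusted p = 0.0076, and adjusted p = 0.23 with an estimated correlation). The MHC class II list fell with 14 of 17 lower and 2 higher against lung DC (adjusted p = 4.2e-10, and adjusted p = 0.048 with an estimated correlation). Against CD103+, CD11b+ and skin LC 13, 13 and 12 were lower and 3, 2 and 3 higher (adjusted p = 3.6e-08, 1.4e-08 and 2.2e-07, and adjusted p = 0.088, 0.08 and 0.098 with an estimated correlation). H2-Aa was at 336 ± 60.8 in macrophages and 18890 ± 2080 in CD103+ LC, and Cd86, a costimulatory ligand, at 4 ± 2.83 and 144 ± 18.3. The MHC class I list fell with 13 of 20 lower and 1 higher against lung DC (adjusted p = 2.8e-05, and adjusted p = 0.12 with an estimated correlation). Against CD103+ LC 11 were lower and 5 higher (adjusted p = 0.038, and adjusted p = 0.44 with an estimated correlation), a call lost without CD103+ replicate 3 (adjusted p = 0.062) or macrophage replicate 1 (0.12).

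The macrophage core genes rose with 23 of 26 higher and 2 lower against lung DC (adjusted p = 3.3e-12, and adjusted p = 0.0083 with an estimated correlation). Against CD103+, CD11b+ and skin LC 17, 17 and 16 were higher and 7, 8 and 5 lower (adjusted p = 0.00017, 3e-04 and 0.0011, and adjusted p = 0.088, 0.12 and 0.15 with an estimated correlation). Mertk, a receptor for apoptotic cells, was at 426 ± 161 and was listed at 0 in skin LC, and Pld3, a lysosomal nuclease, was higher than in CD103+ LC by 4.31 (SE 0.23). Against the 3 LC groups, 12, 10 and 14 of 19 monocyte genes were higher and 3 lower in each (adjusted p = 0.0014, 0.0048 and 0.00052, and adjusted p = 0.088, 0.12 and 0.076 with an estimated correlation). These calls were lost without macrophage replicate 1 (adjusted p = 0.69, 0.86 and 0.4) or 2 (0.66, 0.8 and 0.33), and S100a4 in this list was lower in macrophages by -7.61 (SE 0.16) against CD103+ LC. Inflammatory genes fell with 20, 21, 21 and 19 of 25 lower against lung DC and CD103+, CD11b+ and skin LC, and 2, 2, 2 and 1 higher. The adjusted p-values were 1.2e-08, 9.3e-07, 3.3e-06 and 1.6e-06, and adjusted p = 0.023, 0.06, 0.07 and 0.06 with an estimated correlation. Cd40, a costimulatory receptor, was at 1 ± 1.41 in macrophages and 173 ± 24.9 in CD103+ LC. Immediate-early and stress genes fell with 17, 19, 19 and 18 of 25 lower and 1, 3, 3 and 6 higher (adjusted p = 4e-08, 1.3e-07, 1.2e-07 and 9.3e-07, and adjusted p = 0.12, 0.13, 0.14 and 0.19 with an estimated correlation). Hspa1b, an inducible heat shock protein, was at 10 ± 4.24 in macrophages and 1293 ± 377 in CD103+ LC.

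The migratory DC genes fell in macrophages with 17, 15, 11 and 13 of 23 lower and 1, 4, 4 and 6 higher against lung DC and CD103+, CD11b+ and skin LC. The adjusted p-values were 6.8e-08, 0.00038, 0.02 and 0.048, and adjusted p = 0.023, 0.088, 0.24 and 0.3 with an estimated correlation. The last call was lost without skin LC replicate 1 or macrophage replicate 1 (adjusted p = 0.068 in each). The adhesion and junction list fell with 10, 10, 9 and 11 of 22 lower and 2, 2, 2 and 3 higher (adjusted p = 0.022, 0.014, 0.02 and 0.015, and adjusted p = 0.048, 0.06, 0.07 and 0.06 with an estimated correlation). Epcam was lower than in CD103+ LC by -4.66 (SE 0.19). Against CD103+ and CD11b+ LC the chemokine ligands fell with 9 and 8 of 16 lower and 3 higher in each (adjusted p = 0.038 in both, and adjusted p = 0.44 and 0.45 with an estimated correlation). That was lost without macrophage replicate 1 (adjusted p = 0.38 and 0.37). Pattern recognition receptors rose with 13 and 14 of 23 higher and 8 and 6 lower (adjusted p = 0.038 in both, and adjusted p = 0.099 and 0.12 with an estimated correlation). That call was lost without macrophage replicate 1 (adjusted p = 0.36 and 0.41) or 2 (0.66 and 0.69), and for CD103+ LC without CD103+ replicate 1 (0.052). Ccl6, a chemokine of alveolar macrophages, was at 4530 ± 594 against 9.75 ± 3.1 in CD103+ LC, and Clec7a, the receptor dectin-1, at 738.5 ± 182 against 19 ± 1.63. Against skin LC the cell cycle rose with 17 of 32 higher and 1 lower (adjusted p = 0.0019, and adjusted p = 0.19 with an estimated correlation).

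**Figure D5:**
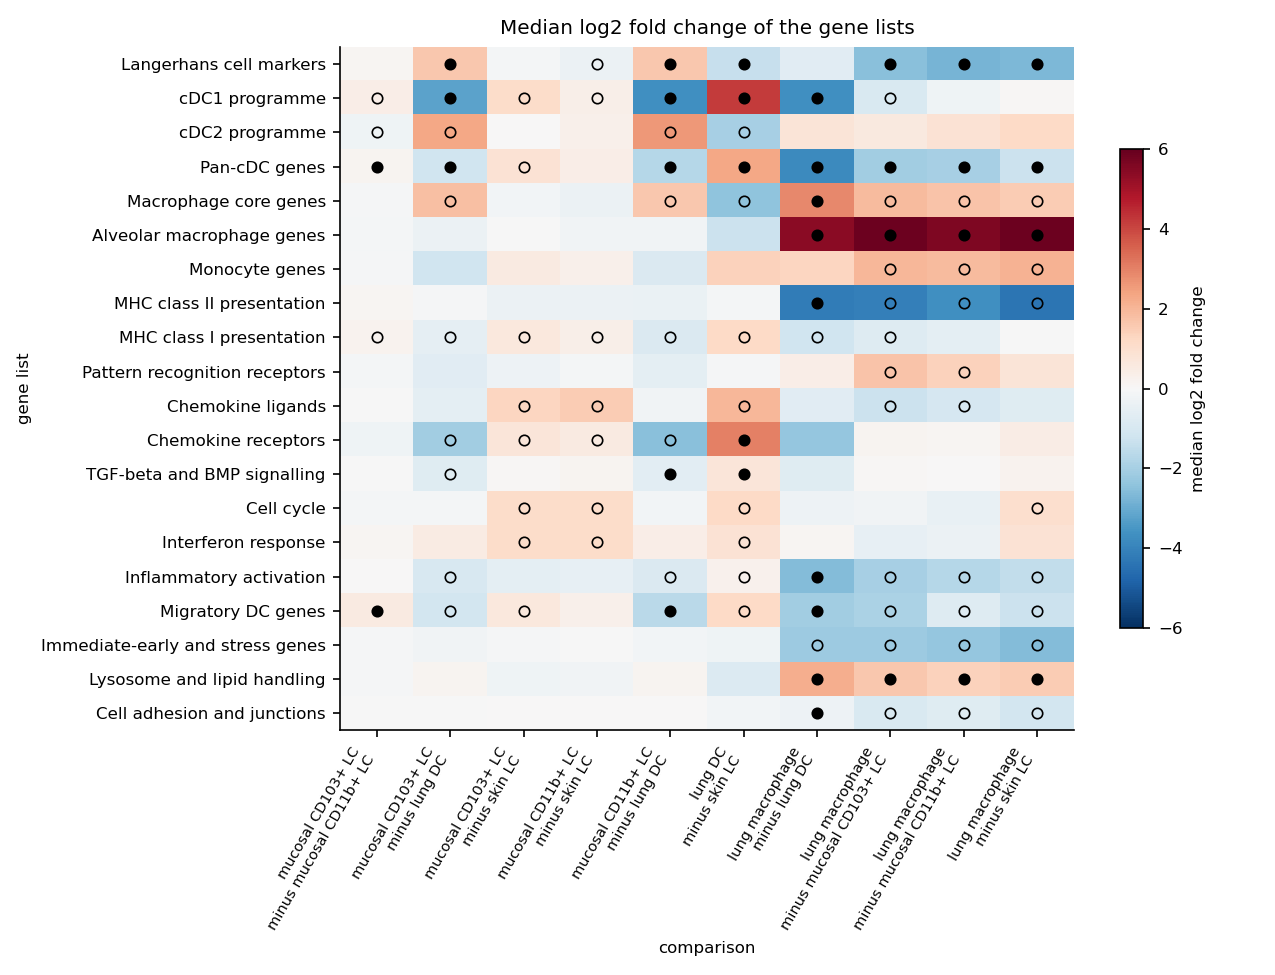
Median fitted log2 fold change of 20 gene lists in the 10 comparisons, from blue (lower in the first group) to red (higher). Circles mark lists called by camera at an adjusted p under 0.05, filled where the call also held with an estimated correlation, as it did for 2 of the 5 lists called between the mucosal subsets.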

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

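The tests with the epithelial and skin LC levels as covariates, of a single source for each set of transcripts and of depth were chosen after the result was seen, while the counts of splits and the test of index exchange were chosen before.

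The 44 genes called between the mucosal subsets were set against other splits of the 8 libraries. Chance could not be excluded, since 3 of the 35 splits, the labelled one among them, called as many genes, with 509 as the highest of the other splits. That split set CD103+ replicate 1 and CD11b+ replicates 2, 3 and 4, the 4 libraries highest in epithelial transcripts, against the rest. A split that followed the skin LC transcripts called 72, so both point to a structure of the samples. Every remaining split called at most 4 genes. With the epithelial level as a covariate 100% of the 44 calls were kept with the same sign, and with the skin transcript level all 44 were. Both levels were spread over the 2 subsets, with mean epithelial shares of 1.43% in CD103+ and 1.70% in CD11b+ LC. Such covariates could hardly move the difference between the subsets (median ratio of log2 fold changes 0.994 with the epithelial level), so keeping the calls decides little. A difference between the sorted subsets stays open, since leaving out the 4 libraries highest in epithelial transcripts left 1 CD11b+ library and cannot decide it.

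Transcripts of stratified epithelium spanned a 12.2-fold range of shares over the mucosal libraries. Depth or scaling moves every gene of a library alike and cancels in a share, so by construction neither could give this range. The comparison with the size factors, which spanned 1.71-fold, therefore tested nothing further. Krt4 was at 8531, 795, 2680 and 2816 in CD103+ replicates 1 to 4 and 937, 4867, 4905 and 4541 in CD11b+ replicates 1 to 4. The 16 abundant members moved together, with a median correlation of 0.984 between a member and the mean of the others across the 8 libraries. RNA of epithelial cells carried along would give such a correlation. The slopes of members on the mean of the others ran from 0.602 (Dmkn) to 1.41 (Krt14), with a median of 0.972. For 1 source of constant makeup every slope would lie near 1, so the correlation alone does not show a single source. Epithelial cells or free RNA in the sorts may still be a source, and a sort on langerin would not remove free RNA. Dcn of the fibroblast list was at 70, 3, 23 and 19 in CD103+ replicates 1 to 4. In CD11b+ replicates 1 to 4 it was at 13, 55, 77 and 60. Gsn of that list stayed between 493 and 581. No biological explanation was tested, and expression of some of these genes by LC themselves stays open.

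Skin LC transcripts stood at 10.8 to 15.2% of the skin level in CD103+ replicates 1 and 2 and CD11b+ replicates 1 and 4, and at 0 to 1.18% in the other 4. Mmp9 was at 83, 104, 146 and 113 in those 4 libraries, against 825 and 1008 in skin LC. The 8 genes behind these shares had a mean of at least 50 in skin LC and a lowest mucosal value of at most 2% of it. That choice built in a low value in some mucosal library and left out genes with a steady mucosal level. It also took in the keratin gene Krt2, so not every member need come from LC. Krt2 stood at 49.5% of the skin level in CD103+ replicate 1 and at 1.83 to 7.34% in the other libraries with the higher shares. In the libraries with the higher shares, on average 84.4% of the 8 genes lay within 2-fold of 1 share of the skin level. For these chosen genes, that is what RNA of skin LC carried along would give. Exchange of sample indexes cannot be told apart from this. Of 1074 genes at 100 or more in each of those libraries, 0 lay under 2% of that in both skin libraries. The lowest stood at 18.2%, so this test could not have decided for or against an exchange. Krt4 was at 505 and 290 in the skin libraries, against 0 and 1 in lung DC. Exchange could leave such values, but their source was not tested. Skin RNA cannot be the whole of the structure. Of the 44 genes that followed the skin level, 20 would need over 50% skin RNA, for example Atp5g3 (98.1%), although all 44 moved toward the skin value.

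Single libraries stood far from the other 3 of their group in 26 of 251 sets of values examined, and the gap over the range is given in brackets. Chance gives about 1 in 20 for independent, normally distributed values. Genes at a few reads and genes that move together break that condition, so the excess over chance was not measured. NK cell genes took 0.00496% of the reads in CD103+ replicate 3 against 0.0024 to 0.00276% in the others (0.859). Erythroid genes took 0.118% in CD103+ replicate 1 against 0.00767 to 0.0152% (0.932). The same library had a correlation of 0.5996 with lung macrophages against 0.641 to 0.646 (0.888). The plasmacytoid DC list took 0.0177% in CD11b+ replicate 1 against 0.0758 to 0.0868% (0.841), which was Ly6d, at 78 against 563 to 637 (0.868), and not Siglech, at 39 against 40 to 54.

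Among the genes, CD103+ replicate 1 was low in Basp1, at 479 normalised reads against 582 to 603 (0.831), in C1qa, at 281 against 419 to 424 (0.965), and in Zmynd15, at 646 against 827 to 862 (0.838). CD103+ replicate 2 was high in Alox5, at 640 against 472 to 497 (0.851), in Flt3, at 117 against 76 to 80 (0.902), in H2-Aa, at 21980 against 17420 to 18130 (0.844), and in Napsa, at 1396 against 973 to 1002 (0.931). CD103+ replicate 3 was high in Abcg1, at 17 against 11 to 12 (0.833), and Marcks, at 206 against 149 to 158 (0.842), and low in Plin2, at 91 against 108 to 110 (0.895). CD11b+ replicate 1 was low in Krt4, at 937 against 4541 to 4905 (0.908), and high in Lyz2, at 222 against 95 to 113 (0.858). CD11b+ replicate 2 was high in Ccl17, at 213 against 130 to 138 (0.904), and in Siglech, at 54 against 39 to 41 (0.867), and CD11b+ replicate 3 in Ccr2, at 11 against 4 to 5 (0.857). Ear2, Lpl, Sftpc, Mertk and Ngp differed by 1 to 3 reads in 1 library (1 each), with Lpl in both mucosal subsets.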

How the results depend on the processing

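Voom, scaling to a common total, both covariates and leaving out the 4 libraries highest in epithelial transcripts were chosen after the data were seen. Of the counts and summary values, 264 recomputed values kept their direction and side of the threshold or stayed within 1.5 times, and 23 moved, 5 weakened and 6 turned. For the gene lists 602 kept their call and 94 lost it, 68 of them with an estimated correlation. For single named genes 6885 were kept, 142 lost the call, 21 gained it and 3 turned. The 44 calls between the mucosal subsets became 14 without the trend, 20 with all 14 libraries and 16 without the 4 libraries highest in epithelial transcripts (1 CD11b+ library left), and 28 to 67 when 1 library was left out. With replicate number as a block they were 39. Libraries of equal number showed no sign of pairing, with correlations of their deviations from the subset means of -0.47 to 0.11. The highest over all pairs was 0.54, for CD103+ replicate 2 with CD11b+ replicate 1, a link the block did not cover. CD103+ replicates 3 and 4 differed little more than read counting gives (chi-square per degree of freedom 1.45, against 3.15 to 9.13 for the other CD103+ pairs). Whether these 2 are separate samples is not known. The 1727 calls between CD11b+ and skin LC became 1021 with the epithelial covariate. With an estimated correlation 2 lists were called between the mucosal subsets, 3 between CD103+ LC and lung DC, 5 each between CD11b+ LC and lung DC and between lung DC and skin LC, 4 each between macrophages and CD103+, CD11b+ and skin LC, and 0 between either mucosal subset and skin LC. When 1 library was left out, calls ranged from 1613 to 2774 between CD103+ LC and lung DC, 1723 to 2966 between CD11b+ LC and lung DC, 664 to 1727 between CD103+ and skin LC, and 650 to 1976 between CD11b+ and skin LC. The lowest of each left 1 library in a group, while against skin LC the calls rose without some mucosal libraries. The difference in similarity to skin LC was -0.0097 over the 1000 most variable genes and -0.0084 to 0.015 when 1 library was left out, and that to macrophages -0.0062 to 0.0092. The correlation of the macrophage and mucosal contrasts ranged from 0.114 to 0.172. Itgae between the mucosal subsets ranged from -0.0713 to 0.0607 (0.0239 without CD11b+ replicate 1), and Cd207 was at -0.3 without the 4 libraries highest in epithelial transcripts. The cause was not tested. Of models for counts, only voom on the recovered reads was run. Depth limits what can be said of genes at a few reads.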

Other observations

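The tests of the shared direction of contrasts and of Itgae against Xcr1 were chosen after the result was seen, while the count of splits for the gene lists and the T cell test were chosen before.

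The following genes were chosen after their values were seen, and no list of them was tested. Alox5, the 5-lipoxygenase, was at 525 ± 77.6 normalised reads in CD103+ LC, 549.5 ± 97.3 in CD11b+ LC (SD, n = 4 each), 1330 ± 109 in skin LC and 0.5 ± 0.707 in lung DC (n = 2 each). Hpgds, which makes prostaglandin D2, was at 390.5 ± 28.2, 350.5 ± 36.5, 563.5 ± 34.6 and 5.5 ± 2.12 in the same order. Alox5ap, which presents the substrate to the lipoxygenase, was at 1232 ± 2.12 in lung DC and 911.5 ± 87 in lung macrophages, against 1470 ± 228 in CD103+ LC. The complement genes C1qb and C1qc, chosen in the same way, were at 139 ± 48.6 and 65 ± 9.76 in CD103+ LC, 196 ± 46.2 and 108 ± 22.8 in CD11b+ LC, and 51.5 ± 2.12 and 26 ± 2.83 in skin LC. Irf4, a transcription factor of cDC2, was at 102 ± 10.7 in CD103+ LC, 138 ± 0 in skin LC and 16 ± 4.24 in lung DC.

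Genes of other cell types took small shares of the reads. Each list is named for its cell type, though 1 member often carried the share, so a share does not show that those cells were present. T cell genes took 0.0194% in CD103+ LC, 0.0167% in CD11b+ LC and 0.0931% in macrophages, where Cd2 was at 630 and 640. B cell genes took 0.0159% in lung DC and 0.0378% in macrophages, NK cell genes 0.00827% and 0.00968%, and endothelial genes 0.0215% and 0.0491%. Neutrophil genes took 0.0981% in skin LC, through Mmp9 with Ngp listed at 0, and 0.272% in macrophages, where Ngp was at 377 and 915. Melanocyte genes took 0.0435% in macrophages, where Gpnmb was at 284 and 430 and Pmel was listed at 0, and mast cell and basophil genes at most 0.00204% in any group mean. Plasmacytoid DC genes took 0.0562% and 0.0659% in the mucosal subsets, mostly Ly6d, which was at 78 to 1142 there and highest where Krt4 was highest, while Siglech was at 14 to 54. Fibroblast genes took 0.0695% and 0.0816%, mostly Gsn, at 493 to 581. Lung epithelium genes took 0.142 to 0.157% in every group. In LC this was mostly Napsa, at 794 to 1646, with Sftpc at 0 to 5, and Sftpc was at 286 ± 49.5 in lung DC and 750 ± 73.5 in macrophages (SD, n = 2 each). Erythroid genes took 0.373% in macrophages, with 0.126% in the lower library. Xist was at 79 and 178 in the macrophage libraries and listed at 0 in the other 12, and Ddx3y was listed at 0 in macrophages and at 26 or more in each of the others.

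Itgae did not differ detectably between the sorts, and cells of the other subset in each sort may be a reason. Had cells of the other subset carried it over, Xcr1 would have followed, yet the log2 fold change of Xcr1 exceeded that of Itgae by 1.89 (SE 0.3), which argues against it. RNA of intraepithelial T cells, which carry CD103, is also argued against, since the CD3 chain genes together reached at most 6.94% of the Itgae level in a mucosal library. The whole T cell list summed to 118 to 206% of the Itgae level, with Cd2 at 63 to 109 and Il7r at 21 to 48, so the verdict rests on the CD3 chains. Protein retained at the surface and control after transcription were not tested.

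For the 5 gene lists called between the mucosal subsets, 9 of the 35 splits called as many lists, with 10 as the highest of the others, so chance could not be excluded. For the correlation of 0.148 between the lung DC to skin LC contrast and the mucosal contrast, 7 of 35 splits gave one as large, with 0.212 as the highest other. For the correlation of 0.162 between the macrophage to lung DC contrast and the mucosal contrast, 1 of 35 splits, the real one, gave one as large, with 0.146 as the highest other. That is the smallest share 35 splits can give, and adjusted over the 2 contrasts the permutation p was 0.0571, so chance is not firmly excluded. The unadjusted permutation p rose to between 0.0571 and 0.114 without CD103+ replicate 2, 3 or 4 or CD11b+ replicate 3 or 4.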
